A study of Mus musculus with 6 samples.

How the data were processed

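Total RNA from 6 mouse hearts at E12.5, dissected in cold buffer and homogenised in TRIzol, was made into libraries with Illumina protocols, per the labels' protocols. Trim Galore and TopHat2 and the genome build mm10 are named in the submitters' processing notes, with no versions. The gene counter, annotation release and strandedness are not given in the sources used here.

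The deposited table holds linear RPKM values made by the authors, with a column for each heart and the constitutive exons used for each of 15118 genes. Its header names no unit, so the unit was taken from the values. In single-exon genes the value times exon length fell on whole multiples of a step in each library, within 0.1 of a step, for 91.6% to 97.7% of low values, against 18.5% to 21.0% (medians) for other steps. The steps imply 132300000, 137900000 and 124200000 reads for controls 2, 5 and 9 and 142200000, 102000000 and 158700000 reads for mutants 5, 8 and 10. The counting error these reads imply had a median SD of 0.023 on the log2(RPKM + 1) scale over 11182 tested genes with an exon length, against a median SD of 0.135 within genotypes, and of 0.034 against 0.138 for the 1997 genes with a mean under 2 RPKM. The table lists only genes whose geometric mean reaches 0.5 RPKM in at least 1 genotype, as checked on its values, and holds no value of 0. No pair of libraries held identical values. Chromosome, start, end and strand come from GENCODE M21 (mm10), which held 14877 of the gene identifiers, and 99.55% of 39402 exon positions named in the table lay inside the gene there.

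The test planned before the data were examined assumed read counts. The file holds RPKM, so the fallback written in the same plan was used. That is limma 3.58.1 in R 4.3.3, with a mean-variance trend on log2(RPKM + 1), genes with at least 1 RPKM in at least 3 libraries (13080 genes, 2038 not tested) and Benjamini-Hochberg adjusted p under 0.05. All 6 hearts entered, with no covariates. All p-values are two-sided. The genotypes share a single sample number, so no block was fitted.

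The genes named are Hif1a, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 value of at least 2 and no overlap between the genotypes, leaving out chromosome Y genes and predicted or non-coding symbols, and up to 4 members with the smallest p of each list. Before the data were examined 22 gene lists were fixed, and 21 had at least 4 tested members. Lists were tested with camera in limma with a preset correlation of 0.01, again with an estimated correlation, and with fry, a rotation test of whether a list's genes move on balance in the same direction. Of 21 lists 11 passed with the preset correlation, 1 (ATF4 targets) with an estimated correlation and 4 (ATF4 targets, HIF1 targets, glycolysis and oxidative phosphorylation) with fry. A further 12 lists were chosen after the main result was seen.

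The fit was tested on simulated data drawn for the 13080 genes of this comparison, with 200 changed genes in each of 5 runs. It recovered 71.2% of genes changed by 0.6 and 95.6% of genes changed by 1 on the log2 scale, with 6.3% false calls. Lists shifted by 0.2 passed in 100% of cases and unchanged lists in 2.5%, with the preset correlation. The simulated genes were drawn independently, so these shares do not hold for lists of correlated members. Estimated correlations of the fixed lists reached 0.755 (macrophage markers). Random lists of 45 genes were used to test the matched-list comparison, and 2.5% of 40 unshifted and 100% of 40 shifted lists exceeded the 97.5th percentile. Genes picked at random do not check lists of correlated members.

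Alternatives were median centring of the log values, no filter on low values, a minimum of 5 RPKM, limma without trend, a robust prior, rescaling by the total without haemoglobin genes, pseudocounts of 0.1 and 5, and leaving out each heart. After the data were seen, 3 further alternatives were added, namely the 4 hearts between the ends of the first principal component, the 4 hearts with chromosome Y expression, and protein-coding genes alone. Tables were handled with Python 3.11.15 and figures drawn with matplotlib 3.10.9.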

Results

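RNA was sequenced from 6 whole hearts of Black-Swiss mouse embryos at E12.5, a stage counted in days after mating, when the heart has its chambers and the ventricular wall is thickening. Each embryo carried the Cre recombinase in the Nkx2-5 gene, which is active in cardiac progenitors and heart muscle and recombines loxP-flanked (floxed) alleles there. The 3 control hearts had a wild-type and a floxed Hif1a allele, and the 3 Hif1a mutant hearts had a null and a floxed allele. Hif1a encodes the oxygen-regulated subunit of the transcription factor HIF1, and the comparison asks which transcripts differ between fetal hearts of these 2 genotypes. By these genotypes cells in which Cre recombined the floxed allele keep 1 functional Hif1a allele in control hearts and none in mutant hearts. The cells without Cre activity differ too, with 2 functional Hif1a alleles in control and 1 in mutant hearts. Expression is given in RPKM (reads per kilobase of constitutive exon, scaled to the reads in the library) as the mean ± SD of 3 hearts, and log2 changes, mutant minus control, were taken on log2(RPKM + 1), which understates the change of genes with low values. The low values imply between 102000000 reads (mutant 8) and 158700000 reads (mutant 10) behind the libraries. Nothing in the labels says more than that the samples are separate hearts, so p-values measure the spread between these samples.

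The hearts correlated between 0.967 and 0.994 over the tested genes. Mutant 5 correlated slightly more with the control hearts (mean 0.988) than with the other mutant hearts (0.985). It lay between controls 5 and 9 on the first principal component. Each other heart correlated more with its own genotype. Control 2 and mutant 8 lay at the ends of the first principal component (45.3% of the variance). The summed RPKM of the 28 copies of 5S ribosomal RNA was lowest in control 2 (10.7) and highest in mutant 8 (192), with 31.2 and 71.9 in controls 5 and 9 and 31.3 and 116 in mutants 5 and 10. By this sum the 6 hearts had the same order as along the first component, and the cause of that order was not tested. Haemoglobin genes took between 3.76% (mutant 5) and 6.12% (mutant 8) of the summed RPKM. The chromosome Y genes Eif2s3y, Kdm5d and Ddx3y were near 0 in control 9 and mutant 8 and expressed in the other hearts, with Eif2s3y between 18.8 and 27.7 RPKM there.

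Hif1a (ENSMUSG00000021109, mm10 chromosome 12, 73901375 to 73947530, plus strand) was not lower in the mutant hearts. It measured 51.3 ± 8.54 RPKM in control and 69.5 ± 12.6 RPKM in mutant hearts (log2 change 0.43 ± 0.16 SE, limma adjusted p = 0.36). The control hearts had 61.2, 46.4 and 46.4 RPKM and mutants 5, 8 and 10 had 75.7, 55.0 and 77.7 RPKM. The value covers the constitutive exons used for the gene together, and which exons the floxed and null alleles lack is not given in the sources used here, so it does not check the deletion.

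The mutant hearts had lower transcripts of HIF1 target genes and glycolytic enzymes and higher transcripts of ATF4 and amino acid response targets. Among 13080 genes tested, 107 passed an adjusted p of 0.05 in limma, 55 of them higher and 52 lower in the mutant hearts. In all 107 the values of both genotypes did not overlap, as in 17% of all tested genes against 10% by chance. Of the 55 higher genes 32 belong to the list of ATF4 and amino acid response targets, and of the 52 lower genes 19 belong to the lists of HIF1 targets and glycolysis. At an unadjusted p of 0.05, 1463 genes passed. The count was 52, 43 and 67 without control 2, 5 or 9 and 198 and 40 without mutant 5 or 10, and higher genes were 51.4% of the calls, against 62.6% (57 higher, 34 lower) after median centring, 40.6% (54 higher, 79 lower) after rescaling without haemoglobin genes and 67.4% (29 higher, 14 lower) without control 5. In the 4 hearts that express chromosome Y genes 53 genes passed, and in the 4 hearts between the ends of the first component 96 passed.

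**Figure D1:**
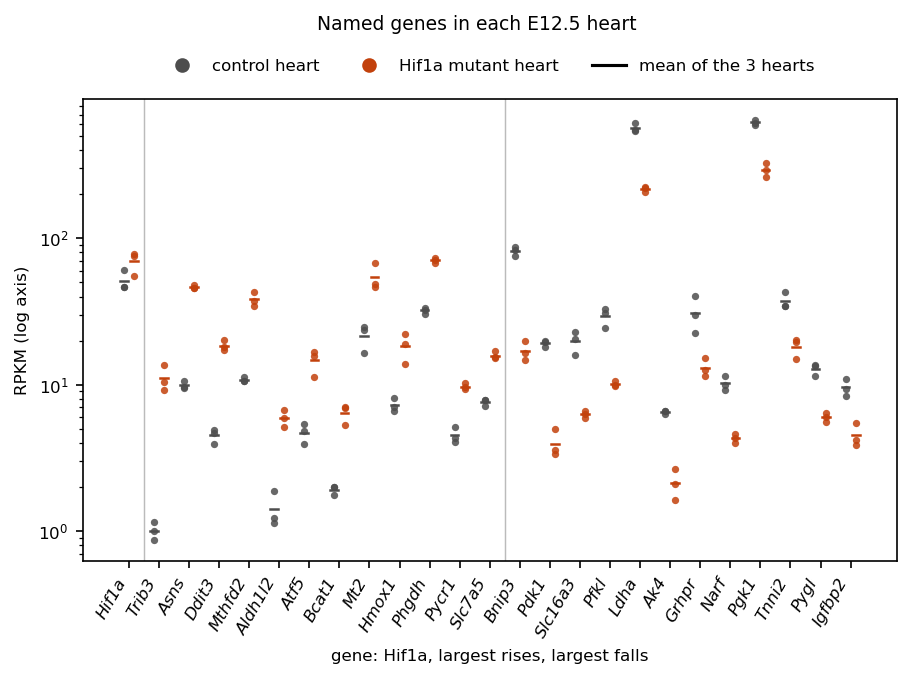
Expression in RPKM (log axis) of Hif1a, the 12 largest rises and the 12 largest falls among genes past the threshold with a mean log2 value of at least 2 (predicted and non-coding symbols and chromosome Y genes left out), with a point for each heart (grey, control; orange, Hif1a mutant) and a line at the mean of 3 hearts. Trib3 averaged 1.01 RPKM in control and 11.1 RPKM in mutant hearts and Bnip3 81.7 and 17.0 RPKM, while the Hif1a values of both genotypes overlap.

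HIF1 target genes other than glycolytic enzymes fell as a group. Bnip3 (ENSMUSG00000078566, chromosome 7, 138890836 to 138909519), which acts in mitophagy and cell death, fell from 81.7 ± 5.78 to 17.0 ± 2.66 RPKM (log2 change −2.21 ± 0.12 SE, limma adjusted p = 7.21e-05). Pdk1 (ENSMUSG00000006494, chromosome 2, 71873224 to 71903858), a kinase that inhibits pyruvate dehydrogenase, fell from 19.2 ± 0.981 to 3.96 ± 0.859 RPKM (limma adjusted p = 0.000133). The lactate exporter Slc16a3 fell from 19.8 to 6.28 RPKM, the adenylate kinase Ak4 from 6.49 to 2.12 RPKM and Narf from 10.3 to 4.30 RPKM. Of 35 tested members 11 fell and none rose, against 21 lower and 1 higher (Stc2) when adjusted over the list alone. The median log2 change was −0.37, and the list passed limma's camera with a preset correlation (adjusted p = 2.84e-18). Its adjusted p = 0.23 with an estimated correlation. The 4 members with a positive change, named after their values were seen, were Stc2 (0.46), Vegfa (0.08), Car9 (0.01) and Ppfia4 (0.00), none past the threshold over all genes, and Vegfa, the vascular growth factor, measured 22.8 RPKM in control and 23.8 RPKM in mutant hearts.

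Glycolytic enzymes were lower in the mutant hearts as a group. Ldha (ENSMUSG00000063229, chromosome 7, 46841475 to 46855627), the lactate dehydrogenase A subunit, fell from 565 ± 40.2 to 216 ± 8.99 RPKM (log2 change −1.38 ± 0.09 SE, limma adjusted p = 0.000232). Phosphoglycerate kinase Pgk1 fell from 619 to 294 RPKM, triosephosphate isomerase Tpi1 from 527 to 283 RPKM and the liver-type phosphofructokinase Pfkl from 29.5 to 10.2 RPKM, while Gapdh measured 1784 and 1378 RPKM (limma adjusted p = 0.24). Of 21 tested members 8 fell and none rose, against 13 lower adjusted over the list alone. The list's median log2 change was −0.46 (limma's camera adjusted p = 1.36e-10). Its adjusted p = 0.34 with an estimated correlation.

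ATF4 and amino acid response targets rose, and this list alone among 21 passed limma's camera also with an estimated correlation. Asparagine synthetase Asns (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254) rose from 9.92 ± 0.633 to 46.5 ± 1.21 RPKM (log2 change 2.12 ± 0.09 SE, limma adjusted p = 2.45e-05). The pseudokinase Trib3 (ENSMUSG00000032715, chromosome 2, 152337422 to 152344032) rose from 1.01 ± 0.138 to 11.1 ± 2.35 RPKM (limma adjusted p = 7.21e-05), and the transcription factor Ddit3 from 4.51 to 18.4 RPKM. The cationic amino acid transporter Slc7a3 rose from 0.317 to 5.67 RPKM. The mitochondrial folate enzymes Mthfd2 (10.8 to 38.3 RPKM) and Aldh1l2 (1.41 to 5.93 RPKM), the serine synthesis enzyme Phgdh (32.2 to 70.7 RPKM), the proline synthesis enzyme Pycr1 (4.52 to 9.70 RPKM) and the transporter Slc7a5 (7.65 to 15.8 RPKM) rose too. Of 47 tested members 32 rose and none fell, against 43 higher adjusted over the list alone, and all 47 had a positive log2 change. The median was 0.76 and the camera adjusted p = 8.61e-76, with an adjusted p = 0.038 with an estimated correlation.

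Other genes with large changes belonged to no fixed list. The branched-chain aminotransferase Bcat1 rose from 1.92 to 6.40 RPKM, metallothionein Mt2 from 21.6 to 54.4 RPKM and haem oxygenase Hmox1 from 7.27 to 18.3 RPKM. The glyoxylate reductase Grhpr fell from 30.8 to 13.1 RPKM, the fast skeletal troponin Tnni2 from 37.2 to 18.2 RPKM, the glycogen phosphorylase Pygl from 12.8 to 6.00 RPKM and the growth factor binding protein Igfbp2 from 9.57 to 4.51 RPKM. Grhpr was not past the threshold without control 5 (limma adjusted p = 0.17) or mutant 10 (adjusted p = 0.15), nor Igfbp2 (0.099 and 0.11). Over 17 alternative settings Grhpr lost its call in 3. Mt2 and Tnni2 were not without control 5 (0.068 and 0.061), nor Hmox1 and Tnni2 without control 2 (0.054 and 0.050). A further 18 calls were predicted, pseudogene or non-coding symbols, 15 lower and 3 higher, the 3 being Gm20652, Gm13054 and 2310061I04Rik, named after their values were seen. The lower ones include the processed pseudogenes Gm3272, Gm5559, Gm12033, Gm4735, Gm2574 and Gm10481. Whether their reads come from related genes was not tested. Some called genes overlap another call on the opposite strand. Shared bases were 2749 for Plekha2 and Gm16933, 2337 for 1110002E22Rik and Gm5105, 735 for Bex1 and Tceal7 and 68 for Ddit3 and Mars. The 107 calls may thus not all be separate.

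Heart muscle genes showed changes in few members. The natriuretic peptide gene Nppa rose from 1036 ± 48.3 to 1740.0 RPKM (log2 change 0.75 ± 0.10 SE, limma adjusted p = 0.012) and Cited1 from 93.7 to 156 RPKM (limma adjusted p = 0.032), the only 2 of 16 trabecular and conduction genes past the threshold. Adjusted over the list alone 3 were higher, with Nppb at 124 and 207 RPKM. This list had a median of 0.11 and a camera adjusted p = 0.0034 (adjusted p = 0.39 with an estimated correlation, and 0.082 without control 2). Its median was 0.002 without control 2, 0.161 without control 5, 0.040 without mutant 10 and 0.002 to 0.523 over all settings, and against the control mean control 5 (0.15) lay among mutants 5, 8 and 10 (0.15, 0.06 and 0.18). Nppa shares 989 of its 1358 bases with the antisense gene Gm13054, and strandedness is not given in the sources used here. Nppa was not past the threshold without control 2 or 5 or mutant 10 (limma adjusted p between 0.052 and 0.074), Cited1 without any heart but mutant 5 (0.061 to 0.17). Over 17 alternative settings Nppa lost its call in 5 (limma adjusted p up to 0.091) and Cited1 in 7 (up to 0.22). None of the 34 sarcomere and contraction genes passed (camera adjusted p = 0.52, median 0.00, mean −0.04), with Myl7 at 1550 and 2066 RPKM and the muscle creatine kinase Ckm at a log2 change of −0.67 (limma adjusted p = 0.11). None of the 16 cardiac transcription factors (camera adjusted p = 0.16) or the 14 compact myocardium genes (0.63) passed, with Hand1 at 7.42 and 11.9 RPKM and Hey2 at 26.4 and 20.6 RPKM.

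Nuclear genes of oxidative phosphorylation were slightly higher as a group. Uqcrq measured 79.4 RPKM in control and 108 RPKM in mutant hearts, Ndufb10 82.2 and 111 RPKM and Cox6a1 316 and 453 RPKM. None of the 51 tested members passed over all genes and 3 were higher adjusted over the list alone. The median was 0.16, with 46 positive members and limma's camera adjusted p = 1.01e-13 (adjusted p = 0.17 with an estimated correlation). Genes with short transcripts had higher log2 changes in general, with medians of 0.06 in the shortest and −0.09 in the longest of 5 groups of protein-coding genes by exon length. None of 27 fatty acid oxidation genes passed (camera adjusted p = 0.13, and 0.046 without mutant 10), with Cpt1b at 45.2 and 56.0 RPKM.

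Markers of macrophages were lower in the mutant hearts. Mrc1, a mannose receptor, measured 5.90 RPKM in control and 2.74 RPKM in mutant hearts, Fcer1g 5.11 and 2.86 RPKM and Cx3cr1 1.76 and 0.835 RPKM. None of 13 tested members passed over all genes and 11 were lower adjusted over the list alone, with all 13 log2 changes negative. The list's median was −0.69 (limma's camera adjusted p = 4.72e-09). Its camera adjusted p = 0.38 with an estimated correlation (0.755), and its fry adjusted p = 0.15. With that correlation the members do not count as separate observations. The medians against the control mean were −0.30, −0.44 and −1.07 in mutants 5, 8 and 10 and between −0.10 and 0.09 in the control hearts. Without mutant 10 the list's median was −0.39, and with a pseudocount of 5 it was −0.28.

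Markers of other cell types moved less. Of 24 epicardial and mesenchymal genes none passed over all genes and 1, Col1a2 (81.8 and 46.6 RPKM), was lower adjusted over the list alone, with a median of −0.24 and a camera adjusted p = 0.000173 (adjusted p = 0.27 with an estimated correlation). Of 25 endothelial and endocardial genes none passed and 5 were lower adjusted over the list alone, with Cldn5 at 2.57 and 1.08 RPKM, a median of −0.12 and a camera adjusted p = 0.0085 (adjusted p = 0.44 with an estimated correlation). That list was not past the threshold without mutant 5 (camera adjusted p = 0.10). Smooth muscle markers (7 tested, camera adjusted p = 0.68), erythroid genes (13 tested, 0.63) and liver, lung, neural and skeletal muscle markers (4 tested, 0.13) did not pass, with 1 smooth muscle gene (Itga8) lower and 2 of the last list (Tubb3, Apoa2) higher adjusted over the list alone. Medians of the erythroid list against the control mean were −0.376, 0.112 and 0.315 in mutants 5, 8 and 10 and −0.08 to 0.07 in the control hearts, and the list passed without mutant 8 (camera adjusted p = 0.045, median −0.13) or mutant 10 (0.032, median −0.24) and in the 4 hearts with chromosome Y expression (0.031, median −0.10), with a median of 0.12 without mutant 5.

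The lists of cell cycle, p53, chaperone, heat shock and immediate early genes had medians between −0.09 and 0.07, with Gadd45a and Sesn2 past the threshold. Cell cycle progression genes had a median of −0.09 (−0.05 after median centring) with 39 of 47 negative and none past the threshold over all genes or adjusted over the list alone (limma's camera adjusted p = 0.018, adjusted p = 0.38 with an estimated correlation), and the list did not pass without control 2 (0.096) or mutant 5 (0.11). Gadd45a, a growth arrest gene, rose from 1.74 to 4.24 RPKM (limma adjusted p = 0.0070), and Cdkn1a measured 4.46 and 7.57 RPKM (adjusted p = 0.077). Of 15 cell cycle inhibitors 1 passed and 3 were higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.54, upward although the median was −0.07). Without mutant 10 the adjusted p of Gadd45a was 0.050, above the threshold. Gadd45a lost its call in 2 of the 16 alternative settings that tested it (limma adjusted p up to 0.069). Of 26 p53 targets only Sesn2, which the ATF4 list also holds, passed (log2 change 0.72 ± 0.11 SE, limma adjusted p = 0.021), 2 were higher adjusted over the list alone, and the list did not pass (camera adjusted p = 0.13, upward with a median of −0.01 and a mean of 0.07). Sesn2 was not past the threshold without control 2, 5 or 9 or mutant 10 (limma adjusted p between 0.077 and 0.12). It lost its call in 6 of the 16 alternative settings that tested it (limma adjusted p up to 0.13). None of 21 endoplasmic reticulum chaperone genes passed (median 0.07, −0.015 without mutant 10 and up to 0.217 over all settings, camera adjusted p = 0.0034, adjusted p = 0.60 with an estimated correlation, and 0.31 without mutant 10). None of 14 genes in the cytosolic heat shock list passed (median 0.07, −0.018 without mutant 10 and up to 0.176 over all settings, camera adjusted p = 0.0091, adjusted p = 0.55 with an estimated correlation, 0.093 without control 5 and 0.31 without mutant 10). That list also holds Hspd1 and Hspe1, which encode mitochondrial chaperones, and Hspe1 (log2 change 0.37) had its smallest p. None of 17 immediate early genes passed (camera adjusted p = 0.16, and 0.035 in the 4 hearts with chromosome Y expression). The genes of mitochondrial DNA were not analysed here.

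**Figure D2:**
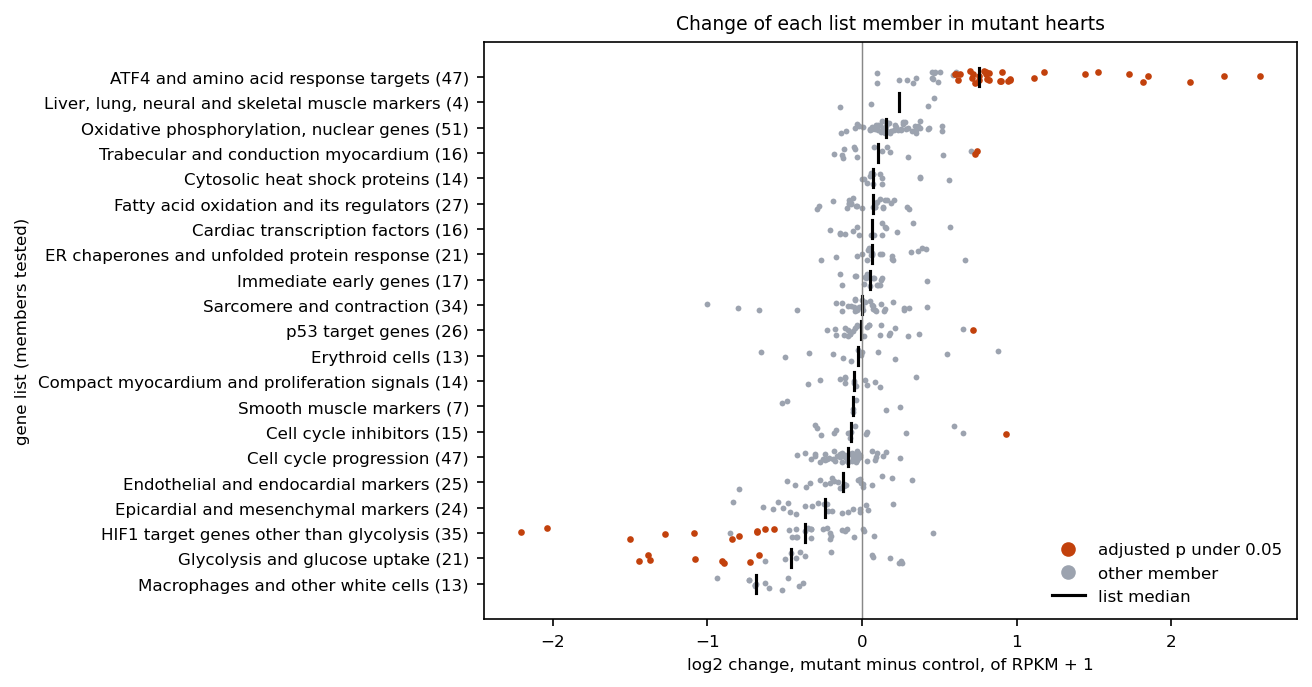
Log2 change, mutant minus control hearts, of log2(RPKM + 1) for each tested member of 21 gene lists, with orange points for members with an adjusted p under 0.05, grey points for the others and a black line at the list median. The ATF4 list has its median at 0.76 with 32 orange points, the HIF1 target list at −0.37 with 11 and the glycolysis list at −0.46 with 8.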

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

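The 3 settings that restrict hearts or genes were chosen after seeing the data. All 107 genes past the threshold, where tested, kept their direction in each setting. Over named genes 1576 values kept their side of the threshold, 23 gained a call and 29 lost it, and no named gene past the threshold changed sign (Stmn2 and Klf6, never past it, did), and over lists 365 kept it, 5 gained and 27 lost. Lower genes numbered 34 after median centring and 79 after rescaling without haemoglobin genes. Leaving out a heart gave between 40 and 198 genes past the threshold, 22 to 85 higher and 14 to 113 lower. In the 4 hearts with chromosome Y expression 53 genes passed, 29 higher and 24 lower, with fewer samples. The log2 change of Hif1a was 0.71 and past the threshold in the 4 hearts between the ends of the first component, and 0.34 to 0.71 over all settings. With an estimated correlation the adjusted p was 0.2298 for HIF1 targets, 0.3434 for glycolysis, 0.3756 for cell cycle progression and 0.1665 for oxidative phosphorylation. The cell cycle list had adjusted p = 0.0721 in the 4 hearts between the ends of the first component, 0.0753 with fry, and 0.0043 to 0.107 without a heart. The cause was not tested for these. Trib3, Asns, Ddit3, Bnip3, Pdk1 and Ldha passed in every setting run. No paired analysis was possible because the genotypes share a single sample number. Count-based tests, voom and the composition setting for mitochondrial genes were not run, since the values are RPKM and those genes were not analysed here.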

Other observations

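The synthetase, folate, non-muscle, mutant 10 and blood tests, the isoform pairs and the 12 lists below were chosen after results had been seen.

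Some glycolytic enzymes and glucose transporters were lower in an isoform while a related isoform did not pass the test. In 7 pairs picked after their values were seen, the ratio of the first to the other was lower in every mutant heart than in every control heart, namely Pfkl to Pfkm, Ldha to Ldhb, Eno1 to Eno3, Pgam1 to Pgam2, Hk2 to Hk1, Slc2a3 to Slc2a4 and Aldoc to Aldoa. Because the pairs were picked from these values, this is a description and no test. Of the first members 5 of 7 fell past the threshold (Pfkl, Ldha, Eno1, Slc2a3, Aldoc) and 0 of the others did in limma, with log2 changes of 0.07 for Pfkm, 0.06 for Ldhb, 0.18 for Eno3, 0.24 for Pgam2, 0.26 for Hk1 and 0.26 for Slc2a4. Aldoa had a negative change, at 691 RPKM in control and 447 RPKM in mutant hearts (log2 change −0.62, limma adjusted p = 0.063).

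Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were higher (20 tested, 8 rose, median 0.46, limma's camera adjusted p = 0.036 with an estimated correlation), and none of 17 mitochondrial synthetases passed (median 0.02, adjusted p = 0.51). Sars rose from 35.4 to 62.9 RPKM and Aars from 11.3 to 20.4 RPKM. The mitochondrial list holds no glycine or lysine enzyme, so it does not cover every synthetase. In the cytosolic list Gars rose (log2 change 0.60, limma adjusted p = 0.021) and Kars did not pass (0.13, adjusted p = 0.63). The 12 cytosolic members that the ATF4 list already held had log2 changes of 0.35 to 0.81, and the 8 outside it −0.03 to 0.22 with none past the threshold. A rise of cytosolic enzymes in general may thus not describe the list, and the mitochondrial median of 0.023 cannot decide it, since 12 of the 20 cytosolic members belong to the ATF4 list, which had already passed. The mean of cytosolic minus mitochondrial enzymes per heart was 1.58 ± 0.11 in control and 1.96 ± 0.08 in mutant hearts (exact permutation p = 0.1, the smallest that 3 against 3 hearts allow).

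Serine, glycine and folate enzymes had 3 of 18 members higher (adjusted p = 0.040 with an estimated correlation), all 3 in the ATF4 list, and the 12 members outside that list had a median of 0.02. A hypothesis was that the mitochondrial folate enzymes alone rise. Their median was 0.614 above that of the 6 cytosolic ones, but Mthfd1l (−0.10) and Mthfd2l (−0.03) lay among the cytosolic values, so it may hold only for Mthfd2, Aldh1l2 and possibly Shmt2 (0.61, limma adjusted p = 0.062), which the ATF4 list holds.

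Among 20 tested NRF2 and oxidative stress targets, a list chosen after the rises of Hmox1 and Mt2 were seen, these and Gsto1 rose. The median was 0.08 (camera adjusted p = 0.040 with an estimated correlation). Because Hmox1 and Mt2 led to the choice of this list, that p describes the values and is no independent test. The other 17 did not pass. Of the 20 members 13 had a positive change, such as Mt1 (0.57), and 7 a negative one, such as Srxn1 (−0.01) and Gclc (−0.06). Mitochondrial ribosomal proteins had a median of 0.13 (57 tested, adjusted p = 0.035 with an estimated correlation) and cytosolic ones 0.17 (56 tested, 0.22), with none past the threshold. Proteasome (31 tested, median 0.08, 0.051), cholesterol synthesis (21 tested, 0.05, 0.21), glycogen metabolism (17 tested, −0.06, 0.41, Pygl lower), fast skeletal isoforms (13 tested, 0.26, 0.55, Tnni2 lower), the 5 mitochondrial folate enzymes (0.61, 0.036) and the 6 cytosolic ones (−0.01, 0.91) complete the lists, each given as tested members, median and camera adjusted p with an estimated correlation.

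Myl6b, an alkali myosin light chain, measured 1.81 and 1.46 RPKM in controls 5 and 9, 47.8 RPKM in control 2 and 53.2, 56.0 and 53.5 RPKM in mutants 5, 8 and 10 (limma adjusted p = 0.27).

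The genotypes differed in 107 genes. Of the 10 splits of the 6 hearts into 3 and 3, only the real one (1 split) gave as many, and the highest other gave 3, but 10 splits are too few for a share under 0.05. Strain variants linked to the null allele were weighed through the position of the calls. Within 10 Mb of Hif1a 0.88% of 113 tested genes passed against 0.82% of 12793 elsewhere (two-sided Fisher's exact test p = 0.61, odds ratio 1.08, interval 0.027 to 6.27), and 104 of 106 located calls lie on other chromosomes, which argues against linkage as the cause of those. It stays open for the 2 located calls on chromosome 12, of which Pygl lies within the window and the other outside it.

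The higher oxidative phosphorylation values may reflect exon length and level at least in part, since 10000 matched lists had a median change of 0.10. That of the 45 members with a length (0.18) lay at percentile 99.9. The matched lists were drawn gene by gene, so their spread does not allow for members that move together. The percentile thus cannot decide whether length and level account for the whole rise. Mitochondrial (0.13 against 0.04, percentile 99.9) and cytosolic ribosomal proteins (0.17 against 0.08, percentile 99.2) also had high percentiles, which are thus not particular to oxidative phosphorylation, and the proteasome lay at 65.4. The cytosolic ribosomal list had an estimated correlation of 0.5 and did not pass camera with it (adjusted p = 0.22). The oxidative phosphorylation median of 0.157 was 0.192 after median centring and 0.114 after rescaling without haemoglobin genes, which argues against normalization between libraries as the whole cause. A lower share of non-muscle cells would raise sarcomere genes alike, and their median was 0.001 with an upper quartile of 0.089. It would also lower non-muscle markers, whose medians were −0.688 (macrophage), −0.238 (epicardial and mesenchymal), −0.121 (endothelial), −0.056 (smooth muscle) and −0.025 (erythroid). The lists thus point both ways, and such a lower share stays open. A difference in oxidative phosphorylation transcripts tied to the genotype stays a hypothesis. That list did not pass camera with an estimated correlation (adjusted p = 0.17), though it passed fry (adjusted p = 0.027). Fry asks whether a list's genes move on balance, and not whether they move more than other genes. A general shift of short genes could thus pass it too. The HIF1 target and glycolysis lists had the same outcome in both tests.

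The lower macrophage markers may rest in part on mutant 10. Without it the list's median was −0.39 against −0.69, and mutants 5 (−0.30) and 8 (−0.44) lay below each control heart (lowest −0.10), which argues against that library as the whole cause. Less blood in the hearts would lower erythroid genes too, but their medians were 0.112 in mutant 8 and 0.315 in mutant 10, above each control heart, and the haemoglobin sum changed by 0.354 and −0.241 on the log2 scale, which argues against it for these 2 hearts. In mutant 5 the erythroid median (−0.376) and the haemoglobin sum (−0.384) were lower too, and a single heart leaves less blood open there. Fewer macrophages in mutant hearts, lower marker transcripts in macrophages with 1 functional Hif1a allele in place of 2, and less other tissue carried along at dissection were not tested.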
